A study of Arabidopsis thaliana with 16 samples.

How the data were processed

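Total RNA of whole Arabidopsis thaliana seedlings was measured on 16 Affymetrix ATH1 arrays, 1 array per sample, with biotin label. The seedlings were wild type of the Wassilewskija (WS) accession or the lhy-21 cca1-11 double mutant in that background, written lhy cca1 here. Seedlings were 9 days old and had grown at 22 °C in cycles of 18 h light and 6 h dark. Per the labels, all had 4 days of cold, 3% sucrose and light of 60 to 65 µE. Each genotype was sampled 15 min before dawn and 15, 30 and 60 min after it, with 2 replicates per genotype and time, which makes 8 groups. No label says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

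The deposited values are intensity on a linear scale. MAS5 and GCOS were used to compute them, per the submitters' processing notes, and their versions are not given in the sources used here. Arrays were labelled by the one-cycle protocol, per the labels' protocols. The deposited intensities had been scaled per array to a common level, as read from the values: with 2% of probe sets trimmed at each end, array means lay between 99.9527 and 99.9563. Array medians lay between 33.6 and 38.3. The table held 22810 probe sets, of which 64 controls (0.281%) were left out of the tests, leaving 22746.

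Genes were named only through the annotation table given for this array, with symbols updated through a reference gene table of the TAIR10.1 assembly. It lists 1 gene for 13513 probe sets, several for 503 and none for 8730. Of the probe sets with 1 gene, 13436 matched the reference table. Probe sets with several genes or none listed are given by their identifier. CCA1, LHY, TOC1 and PRR9 had no named probe set here, so the genes targeted by the mutations were not used to check the genotype labels.

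Values were converted to log2 without an offset. A probe set was tested if it lay above its array's 40th percentile (19.1 to 22.0) on at least 2 arrays. This left 14878 probe sets, of which 8049 were named, for 7972 genes. A total of 60 genes had more than 1 tested probe set. In lists and among named genes each gene was represented by its probe set of highest mean signal. limma 3.58.1 in R 4.3.3 fitted 8 group means (lmFit, then eBayes with an intensity trend), with 8 residual degrees of freedom. Benjamini-Hochberg adjusted p under 0.05 was the threshold in each comparison, and all tests were 2-sided. All adjusted p-values of single genes are from limma, and ± after a log2 value is its standard error in that fit, with 2 arrays per group. Where a group lay below the 40th percentile on all its arrays, the signal is called dim and the difference is given as a lower bound ("at least N-fold"), the brighter mean set against the higher of that percentile and the dim signal. No fold is given where that bound is under 1 or both groups are dim. For named genes dim at some times, the genotype difference is given at single times or only as past the threshold.

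The comparisons were genotype as the mean over 4 times and at each time, each time after dawn against the time before it in either genotype, and the genotype by dawn interaction. F tests covered the 3 times after dawn together. Y candidates were probe sets that rose at least 2-fold past the threshold in WS at 15, 30 or 60 min and were also at least 2-fold higher in lhy cca1 in the mean over 4 times.

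Gene groups were compared with the other tested genes by camera with a preset correlation of 0.01, and again with an estimated correlation. There were 23 lists and 10 comparisons. The lists were also tested by fry, which asks whether members change, without comparing them with other genes. Camera tests for a shared direction, and fry was run by direction and in either direction. Adjusted p-values of a list run over the lists of 1 comparison. Of the lists, 21 had been fixed from textbook knowledge, but most of them had fewer than 3 tested members on this annotation. A further 17 lists were drawn from the genes the annotation names, after the annotation was seen and before any fit. Design, rules and the first lists were fixed before the data were examined. Named genes followed a rule: in the genotype comparison the 8 highest and 8 lowest with the same sign at all 4 times; around dawn the 8 largest rises and 8 largest falls at 60 min in which both later arrays lay beyond both earlier ones, and up to 4 rises at 15 min; up to 12 genes for the interaction; and up to 10 Y candidates. Up to 4 members of each described list were also named by smallest adjusted p. GI was always named.

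The fit was tested on simulated data with 200 changed probe sets among 14878. Over 5 simulations it recovered 96.4% of 2-fold changes for the genotype mean, 70.2% for dawn in WS at 60 min and 38% for the interaction at 60 min. At 4-fold the shares were 100%, 97.4% and 85.6%. False calls averaged 7.6, 10.2 and 9.6 per simulation, in the same order. The simulated noise was independent between probe sets and arrays, so errors under correlated noise were not assessed.

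Alternatives were quantile normalization, median centring, an offset before the log, other filters, eBayes without the trend, and the replicate number as a block. Further ones were fits of only the arrays of 1 time (genotype) or 1 genotype (dawn), a 2-fold criterion, and leaving out each array in turn. After the data were seen, the 25S rRNA control signal as a covariate and the omission of the 4 lhy cca1 replicate 2 arrays were added, as was the replicate number as a term in the fit of the plastid list mean. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 drew the figures. The number of arrays limits the precision.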

Results

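Transcript levels were measured in 16 samples of 9-day-old seedlings, with 2 samples for each of WS and lhy cca1 at 15 min before dawn and at 15, 30 and 60 min after it. LHY and CCA1 are related transcription factors of the morning part of the plant circadian clock, and both are disrupted in lhy cca1. The series title asks for candidates for Y, a component that models of this clock had proposed as induced by light and repressed by LHY and CCA1. Replicates of a group correlated at 0.961 to 0.981 across probe sets, lowest for WS at 60 min. The first principal component held 29.7% of the variance and the second 18.4%.

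Transcripts differed between lhy cca1 and WS seedlings in both directions in the mean over 4 times. This comparison asks which transcripts depend on LHY and CCA1 around dawn. GI, which encodes GIGANTEA, a protein of the evening clock and of day-length-dependent flowering, was higher in lhy cca1 by 2.15 ± 0.433 log2 at 60 min (adjusted p = 0.0116) and at least 2.88-fold at 30 min, when it was dim in WS (adjusted p = 0.0414). It was dim in both genotypes before dawn and at 15 min, so the test of its mean over 4 times (adjusted p = 8.56e-05) rests partly on dim signals. SEC, which encodes an O-linked N-acetylglucosamine transferase, was lower in the mean over 4 times (adjusted p = 5.32e-12). It differed by -3.49 ± 0.231 log2 at 15 min and by -2.83 ± 0.231 at 60 min, with 1 of 2 lhy cca1 arrays above the 40th percentile at each, and was at least 7.58-fold lower before dawn and 10.5-fold lower at 30 min, when it was dim in lhy cca1. Its signal before dawn was 162.3 ± 10.5 (SD, n = 2) in WS and 11.95 ± 2.34 (SD, n = 2) in lhy cca1. AT3G62550 was higher by 2.33 ± 0.0917 log2 (adjusted p = 3.84e-11), with 148.0 ± 15.6 (SD, n = 2) in WS and 596.6 ± 63.1 (SD, n = 2) in lhy cca1 before dawn. AT2G25510 was lower, at -2.11 ± 0.119 log2 (adjusted p = 6.34e-09).

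A total of 2709 of 14878 probe sets differed between genotypes in the mean over 4 times, 1616 of them higher and 1093 lower in lhy cca1. Of these, 100 were at least 2-fold higher and 54 at least 2-fold lower. With each array centred on its median, 2747 differed and the balance turned to 1340 higher and 1407 lower. With the 25S rRNA control signal as a covariate 1182 passed (731 higher, 451 lower), and without the 4 lhy cca1 replicate 2 arrays 872 did (523 higher, 349 lower). Among named genes with the same fitted sign at all times, AT2G30600 was also higher (1.68 ± 0.125), as were AT5G62280 (adjusted p = 9.28e-06), AT2G03310 (adjusted p = 0.000247) and AT1G11210 (adjusted p = 1.41e-05), which were dim in WS at 2 or more times. AT5G62280 differed by 2.35 ± 0.538 before dawn and by 1.92 ± 0.538 at 15 min (adjusted p = 0.0877). It was at least 2.63-fold higher at 30 min, not past the threshold singly, and at least 1.79-fold higher at 60 min. AT2G03310, above the 40th percentile on 1 of 2 WS arrays at either early time, differed by 0.04 ± 0.588 before dawn (adjusted p = 0.989) and by 1.46 ± 0.588 at 15 min (adjusted p = 0.252), and was at least 1.76-fold and 2.52-fold higher at 30 and 60 min. AT2G30600 had a further probe set, at 1.89. AT1G17665 was dim in WS and at least 1.19-fold higher in lhy cca1. AT5G62360 was also higher (adjusted p = 0.000232) but dim in WS, and its bound gave no fold. On the lower side, AT1G10850 differed by -1.49 ± 0.0966 and AT5G45690, dim in lhy cca1 at 30 and 60 min, was at least 1.11-fold and 2.62-fold lower there, neither past the threshold singly (adjusted p = 0.612 and 0.134). AT1G26790 was dim in lhy cca1 and at least 1.32-fold lower. AT5G62210 and AT1G01130 (dim in lhy cca1 at 2 and 3 of 4 times), AT5G59680 (dim in WS) and AT1G14950 (dim in lhy cca1) also passed. Their calls were lost on leaving out single arrays, among them WS before dawn replicate 1 for AT5G62210 (adjusted p = 0.0553), AT1G01130 (adjusted p = 0.054) and AT5G59680 (adjusted p = 0.0672), and WS 15 min replicate 1 for AT1G14950 (adjusted p = 0.0581). AT5G52660, the 1 tested member of the morning clock list, differed by 0.02 ± 0.112 log2 (adjusted p = 0.919), and its sign turned under quantile normalization and median centring. The largest fitted differences were in probe sets with no gene listed. Of these, 261569_at (at least 60-fold to 86.5-fold lower at the single times) and 266719_at (at least 31.6-fold lower at 60 min) were dim in lhy cca1. On the higher side, 249741_at was dim in WS (at least 1.62-fold to 8.46-fold higher), and 248910_at differed by 2.31 ± 0.386 at 30 min and 3.52 ± 0.386 at 60 min (1 of 2 WS arrays above the 40th percentile) and was dim in WS at the earlier times. These 4 were chosen after their values were seen.

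**Figure D1:**
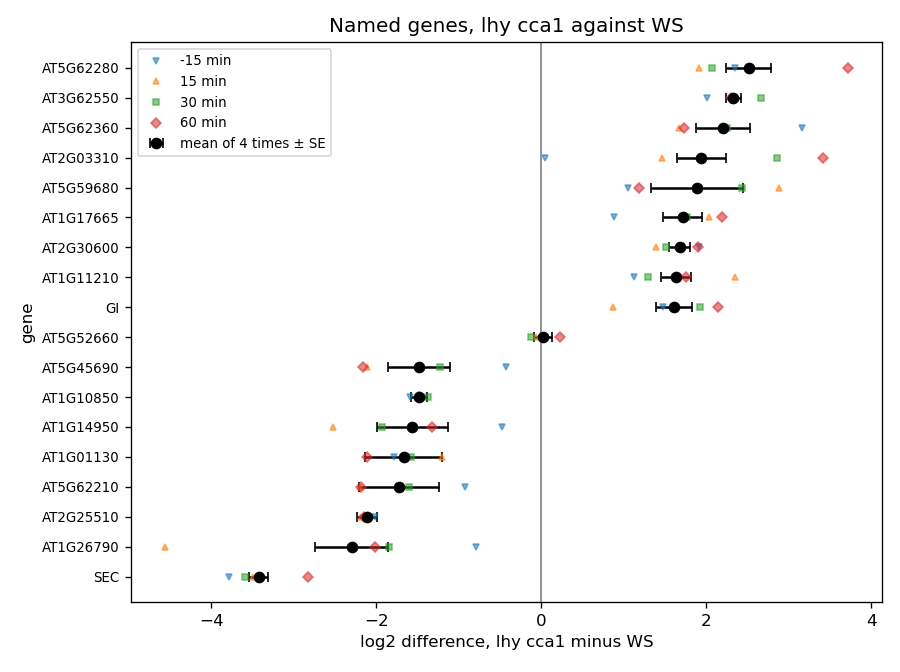
Differences between lhy cca1 and WS (log2) for the genes named by rule and AT5G52660; black points and bars are the mean over 4 times with its standard error, and coloured symbols are the single times. Many values involve dim signals. Among genes with no dim group, AT3G62550 lies at 2.33 and AT2G25510 at -2.11.

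Genes encoded in the plastid genome were higher in lhy cca1. Of 65 tested, 31 were higher, 0 lower and 34 did not pass in limma, and the list's median difference was 0.38. The 4 with the smallest adjusted p were ndhE (0.69 ± 0.114) and ndhA (0.51 ± 0.0979), subunits of the plastid NADH dehydrogenase-like complex, and the ribosomal protein genes rpl14 (0.87 ± 0.153) and rpl16 (1.02 ± 0.192). The list differed from other genes by camera (adjusted p = 3.29e-10; adjusted p = 0.31 with an estimated correlation). The mean 25S rRNA control signal was also higher in lhy cca1, at 7.76 ± 1.27 (SD, n = 8) log2 against 6.57 ± 0.523 (SD, n = 8) in WS. The difference was 1.2 (exact permutation test, 2-sided p = 0.0309). Most of it lay in the lhy cca1 replicate 2 arrays, which averaged 8.74, while the lhy cca1 replicate 1 arrays averaged 6.79. The test takes no account of replicate number. Its p-value therefore cannot tell a genotype difference from one confined to those replicate 2 arrays. The list mean differed by 0.431 ± 0.126 log2, by 0.258 ± 0.125 (95% interval -0.0202 to 0.537) with 25S rRNA as a covariate, and by 0.244 ± 0.139 without the 4 lhy cca1 replicate 2 arrays.

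**Figure D2:**
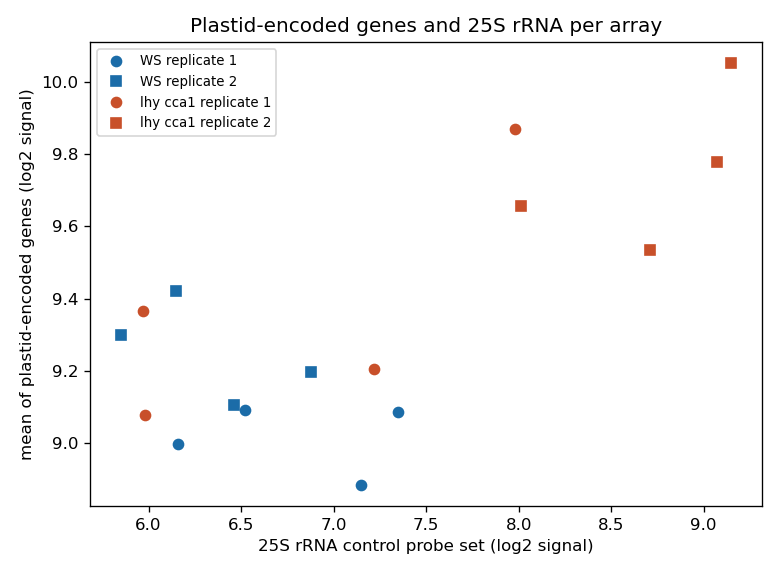
Mean log2 signal of the 65 plastid-encoded genes (vertical) against the 25S rRNA control probe set (horizontal), 1 point per array, coloured by genotype and shaped by replicate number. The lhy cca1 replicate 2 arrays average 8.74 for 25S rRNA and the WS arrays 6.57.

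Phenylpropanoid and flavonoid genes were lower in lhy cca1, with 5 of 11 lower, 0 higher and 6 not past the threshold (camera adjusted p = 5.68e-04; adjusted p = 0.275 with an estimated correlation). CHIL, a chalcone isomerase-like protein gene of flavonoid synthesis, was lower at -0.94 ± 0.104 log2. The flavonol glycosyltransferase genes UGT78D1 (-0.70 ± 0.11) and UGT78D2 (-0.41 ± 0.0825) were lower, as was HCT (-0.30 ± 0.0701), which acts in the synthesis of lignin precursors. Sugar starvation genes were higher (camera adjusted p = 0.00587; adjusted p = 0.275 with an estimated correlation), with 2 of 3 higher and all 3 higher when adjusted over the list alone. The 2 were MCCA (0.98 ± 0.128) and IVD (0.86 ± 0.108), which act in leucine breakdown. Of 11 amino acid breakdown genes 4 were higher and 1 lower, a list that shares these genes and did not pass (adjusted p = 0.0951). Among the light-harvesting proteins, LHCB4.3 was lower at -1.06 ± 0.111 and LHCB4.1 higher at 0.32 ± 0.0614, and the list did not pass (adjusted p = 0.98). Of 3 chlorophyll synthesis genes, PORB (0.45 ± 0.096) and CHLM (0.33 ± 0.0762) were higher, and all 3 were higher when adjusted over the list alone; the list passed under quantile normalization (adjusted p = 0.0132) and not otherwise (0.0539). Of 10 tetrapyrrole synthesis genes 4 were higher and 0 lower, with the same dependence (0.0156 under quantile normalization, 0.0865 otherwise). The cold-regulated genes COR47 (0.57 ± 0.0829), COR15B (0.51 ± 0.128) and LTI30 (0.78 ± 0.1) were higher. COR15B passed singly at 60 min alone (1.82 log2) and had the opposite sign before dawn (-0.35, adjusted p = 0.586). COR47 and COR15B are 2 of 3 tested cold response genes, and also 2 when adjusted over the list alone (list adjusted p = 0.0865). HAT2, a homeodomain gene of the shade response, was higher at 0.61 ± 0.0869.

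At single times fewer probe sets differed between genotypes. The counts were 239 before dawn (139 higher, 100 lower), 257 at 15 min (170 and 87), 159 at 30 min (99 and 60) and 505 at 60 min (355 and 150). Median centring gave 71 higher and 68 lower at 30 min. With only the arrays of each time fitted, 299, 647, 208 and 88 differed, so the order of the times is not settled. GI, dim in both genotypes before dawn and at 15 min, did not pass then (adjusted p = 0.106 and 0.372). Leaving out 1 array moved the counts of the main fit by more than 1.5 times. The lowest were 45 before dawn without lhy cca1 before dawn replicate 2, and 25, 26 and 141 at 15, 30 and 60 min, each without lhy cca1 replicate 2 of that time.

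Within the hour around dawn, transcripts of WS seedlings changed in both directions. The comparison of each time with 15 min before dawn asks which transcripts change around lights-on. No sample was kept dark past dawn, so a response to light cannot be told apart from a change with time. AT1G48100 rose by 3.33 ± 0.198 log2 at 60 min (adjusted p = 1.74e-08), from a signal of 34.29 ± 7.73 (SD, n = 2) to 342.1 ± 39.5 (SD, n = 2). PUB19, which encodes a U-box ubiquitin ligase, rose by 3.06 ± 0.377 log2. GI, dim before dawn, rose at least 4.23-fold, to 86.33 ± 8.44 (SD, n = 2). AT5G61590 fell by 3.42 ± 0.190 log2 (adjusted p = 1.12e-08), from 235.7 ± 35.4 (SD, n = 2) to 22.01 ± 2.64 (SD, n = 2).

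In WS, 19 probe sets changed at 15 min (7 up, 12 down), 319 at 30 min (135 up, 184 down) and 1327 at 60 min (526 up, 801 down), and 1029 passed the F test over the 3 times. Median centring gave 644 up and 636 down at 60 min. At 15 min the 1 named rise was AT5G15950 (1.07 ± 0.118 log2, adjusted p = 0.00125). Other rises at 60 min started from dim signals and are given as bounds: AT2G27420 at least 15.7-fold, the senescence-associated sugar transporter gene SAG29 at least 6.77-fold and the RING-finger gene ATL5 at least 1.31-fold. AT1G49200 fell by 3.13 ± 0.256 log2, and AT2G20670 fell by 2.63 ± 0.191. AT4G10910 fell at least 4.27-fold and AT5G62280 at least 1.64-fold, both to dim signals. UGT84A1 and AT3G56260 (rises, at least 1.47-fold and 2.80-fold) and AT2G25200, AT4G04630 and AT5G49170 (falls, at least 1.78-fold, 2.41-fold and 1.1-fold) passed with all arrays. All but AT5G49170 lost the call without WS 60 min replicate 1 and without WS before dawn replicate 2, UGT84A1 also without either other array of the contrast, and AT5G49170 without WS before dawn replicate 1 (adjusted p = 0.0546). The others then had adjusted p from 0.0526 to 0.105. The count at 60 min was 822 and 849 without WS before dawn replicate 1 or 2.

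Among WS gene groups, phenylpropanoid and flavonoid genes rose at 60 min, 5 of 11 up and 0 down (camera adjusted p = 9.99e-04; adjusted p = 0.287 with an estimated correlation). UGT78D2 rose by 1.77 ± 0.165 log2, UGT78D1 by 1.15 ± 0.221 and UGT84A3, another glucosyltransferase gene, by 0.95 ± 0.175. Wall-loosening genes went both ways, 3 up and 5 down of 18 (camera adjusted p = 0.357). The list passed by fry, which does not compare with other genes (adjusted p = 0.0099 by direction and 9.65e-08 in either direction). EXO differed by -1.47 ± 0.172, the xyloglucan endotransglucosylase gene XTH16 by -1.25 ± 0.19 and the expansin gene EXPA8 by -0.96 ± 0.174, all falls, and XTH32 rose by 1.17 ± 0.138. AKINBETA1, a regulatory subunit gene of the energy-sensing kinase SnRK1, fell by 1.96 ± 0.222. It was the 1 change among 3 sugar starvation genes, also when adjusted over the list alone. The list did not pass (camera adjusted p = 0.0745, and 0.492 with an estimated correlation), but did with the replicate number as a block (0.0383). SMZ, a floral repressor gene above the 40th percentile on 1 of 2 arrays before dawn, rose by 2.35 ± 0.283 and MGL, a methionine gamma-lyase gene, by 1.40 ± 0.169. LEA4-5, a late embryogenesis abundant protein gene, rose at least 4.32-fold. At 30 min nuclear photosynthesis genes stood higher as a group (camera adjusted p = 0.00263; adjusted p = 0.521 with an estimated correlation), with 0 of 21 past the limma threshold singly. Light-harvesting proteins did so too (adjusted p = 0.0429; adjusted p = 0.466 with an estimated correlation), with 0 of 3 past the limma threshold and 2 adjusted over the list alone, and not under quantile normalization (0.066). At 30 min 1764 of all probe sets had an unadjusted p under 0.05.

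Dawn was also followed by changes in both directions in lhy cca1. AT1G48100 rose by 3.07 ± 0.198 log2 at 60 min. PUB19 rose by 4.45 ± 0.377 (adjusted p = 1.03e-06; 3.13 to 5.41 over the alternatives), from a signal above the 40th percentile on 1 of 2 arrays before dawn. GI rose at least 17.9-fold, from a dim signal to 383.3 ± 31.3 (SD, n = 2). AT3G15450 fell by 3.36 ± 0.250 log2 (adjusted p = 2.41e-07), AT5G61590 fell by 3.05 ± 0.190, and AT3G06070 fell by 3.09 ± 0.243, to a signal above the 40th percentile on 1 of 2 arrays. COR15A, a cold-acclimation gene of the chloroplast stroma, rose at least 4.19-fold, and its relative COR15B by 1.71 ± 0.256 log2.

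Counts in lhy cca1 were 12 at 15 min (3 up, 9 down), 259 at 30 min (113 up, 146 down) and 1415 at 60 min (642 up, 773 down), with 1042 past the F test. Median centring gave 729 up and 675 down at 60 min. At 15 min AT5G15950 rose by 0.82 ± 0.118 log2 (adjusted p = 0.0201) and AT3G44450 by 1.00 ± 0.179 (adjusted p = 0.0438). AT5G15950 lost the call without lhy cca1 15 min replicate 1 (adjusted p = 0.0959) or 2 (adjusted p = 0.179) or lhy cca1 before dawn replicate 2 (adjusted p = 0.0759), and AT3G44450 without any of 12 arrays taken singly (adjusted p up to 0.931). Further rises at 60 min from dim signals were AT2G27420 (at least 6.04-fold), AT5G17780 (at least 1.52-fold), AT3G56260 (at least 1.49-fold) and AT5G66740 (at least 1.46-fold). UGT84A1 rose (adjusted p = 0.00159) with no fold to give. AT4G10910 fell at least 8.18-fold and AT1G33055 at least 1.82-fold, and AT4G26540 fell to a dim signal with no fold to give. AT2G25200 (at least 3.22-fold) and AT1G09575 (at least 1.23-fold) fell with all arrays and lost the call without lhy cca1 before dawn replicate 1, before dawn replicate 2 or 60 min replicate 1 (adjusted p from 0.0545 to 0.143). The count at 60 min was 910 without lhy cca1 60 min replicate 1 and 797 without lhy cca1 before dawn replicate 2. Without the 4 lhy cca1 replicate 2 arrays 297 probe sets passed the F test, 131 up and 166 down, and 279 of them were among the 1042.

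Phenylpropanoid and flavonoid genes rose in lhy cca1, 5 of 11 up and 0 down (camera adjusted p = 2.35e-04; adjusted p = 0.0984 with an estimated correlation). UGT78D2 rose by 1.52 ± 0.165 log2, UGT78D1 by 1.74 ± 0.221 and UGT84A3 by 1.02 ± 0.175. Cold response genes rose, 2 of 3, and 3 adjusted over the list alone (camera adjusted p = 4.22e-04; adjusted p = 0.0984 with an estimated correlation), and the wider cold and dehydration list had 4 of 13 up and 1 down (adjusted p = 0.00545; adjusted p = 0.214 with an estimated correlation). AKINBETA1 fell by 2.34 ± 0.222, the 1 of 3 sugar starvation genes past the threshold (2 adjusted over the list alone; camera adjusted p = 0.0287; adjusted p = 0.396 with an estimated correlation). Auxin-related genes were lower as a list (adjusted p = 0.043; adjusted p = 0.214 with an estimated correlation), with 2 of 8 down, among them IAA18, an auxin response repressor gene, which fell by 1.05 ± 0.18. ATG8E, a gene of autophagosome formation, fell by 1.80 ± 0.281. EXO differed by -1.86 ± 0.172, XTH16 by -1.28 ± 0.19 and EXPA8 by -1.15 ± 0.174, all falls, and XTH32 rose by 1.18 ± 0.138. Their wall-loosening list had 3 up and 3 down of 18 (camera adjusted p = 0.36). It passed by fry (adjusted p = 0.0137 by direction and 3.61e-08 in either direction). At 15 min plastid-encoded genes stood higher than before dawn as a list (camera adjusted p = 4.72e-20; adjusted p = 0.65 with an estimated correlation), with 0 of 65 past the limma threshold singly and 736 of all probe sets at an unadjusted p under 0.05. The 25S rRNA signal moved too, from 5.98 and 9.07 log2 on the 2 arrays before dawn to 7.98 and 9.15 at 15 min, while the list mean went from 9.079 and 9.778 to 9.868 and 10.05. The list mean differed by 0.528 ± 0.264 log2 (95% interval -0.0805 to 1.14), and by 0.4 ± 0.25 with 25S rRNA as a covariate.

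Dawn changes of both genotypes were compared over all 14878 probe sets; genes are not independent replicates. At 60 min they correlated with Pearson's r = 0.664 and Spearman's rho = 0.507 across probe sets, with no array shared between the comparisons. Of the probe sets called in WS, 95.3% had the same sign in lhy cca1. Of 791 called in both, 789 had the same sign, 350 up where 22.7 would be shared by independent lists, and 439 down where 41.6 would. At 30 min r was 0.453 and 171 of 171 shared calls had the same sign.

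**Figure D3:**
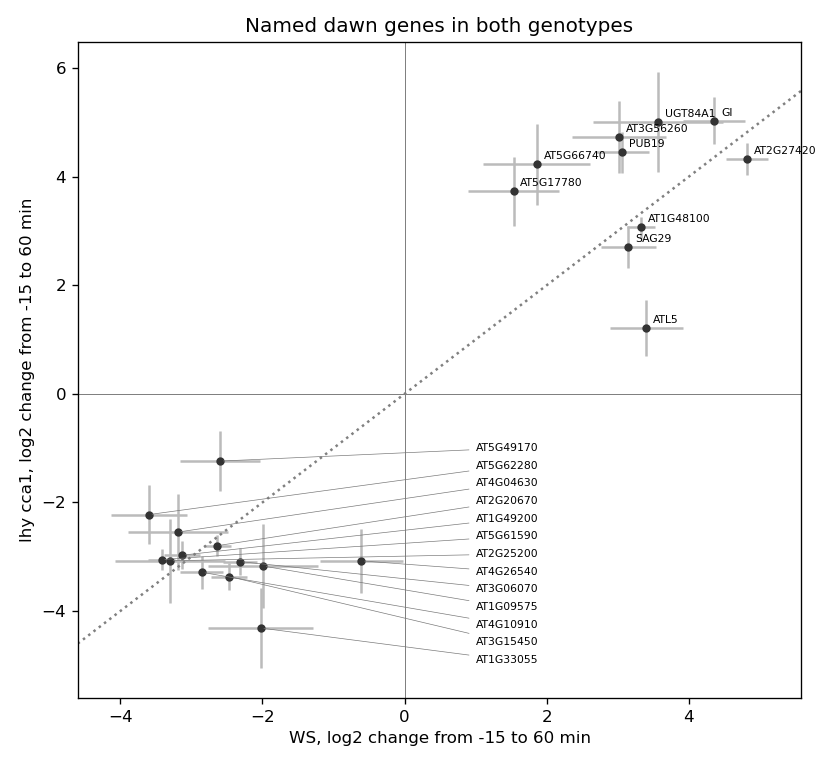
Change from 15 min before to 60 min after dawn (log2) of the named dawn genes in WS (horizontal) and lhy cca1 (vertical); points are estimates, bars standard errors, the dotted line marks equal change, and many values involve dim signals. All points lie in the quadrants of equal sign, with AT1G48100 at 3.33 and 3.07 and AT5G61590 at -3.42 and -3.05.

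The test of whether dawn changes differ between genotypes named 1 gene, AT4G33380 (F test adjusted p = 0.00709), whose interaction was 1.13 at 15 min, -0.90 at 30 min and 0.79 log2 at 60 min (standard error 0.24), none past the threshold singly. Its F test call was lost with eBayes without the trend (adjusted p = 0.187) and without WS 30 min replicate 1 (adjusted p = 0.0714). Past the F test were 4 probe sets, 2 higher and 2 lower at their largest time (3 under quantile normalization, 2 and 1), against 611 at an unadjusted p under 0.05. With eBayes without the trend 0 passed the F test and 1, 250665_at, passed at 60 min. The 3 without a listed gene were chosen after their values were seen. The signal of 250665_at rose by 2.50 log2 in WS at 60 min and changed by 0.25 in lhy cca1 (interaction -2.25 ± 0.22, adjusted p = 2.24e-04). That of 256266_at rose by 2.38 and 1.04 (interaction -1.34 ± 0.209, adjusted p = 0.0371). For 253971_at the values were -1.15 and 0.67 (interaction 1.82 ± 0.253, adjusted p = 0.0133). In the mean over 4 times 250665_at and 256266_at were higher in lhy cca1, by 0.76 ± 0.0777 and 0.35 ± 0.0738 log2. The smaller rises of these in lhy cca1 are therefore not lower mean levels. In the same mean 253971_at differed by -0.99. Of 23 alternatives, the F test call of 250665_at was lost under 1, that of 253971_at under 12 and that of 256266_at under 17, and at 60 min the calls of the latter 2 were lost under 4 and 11. At 15 and 30 min limma called 0 probe sets, against 634 and 695 at an unadjusted p under 0.05. Leaving out single arrays moved the F test count between 1 (without WS 30 min replicate 1) and 7 (without lhy cca1 before dawn replicate 1).

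The dawn change of cold response genes differed between genotypes as a list. At 60 min it was higher in the interaction (camera adjusted p = 3.05e-05; adjusted p = 0.0441 with an estimated correlation). COR15A (1.86 ± 0.542 log2, adjusted p = 0.481), COR15B (2.18 ± 0.363, adjusted p = 0.0615) and COR47 (0.53 ± 0.234, adjusted p = 0.682) did not pass singly, and 3 of 3 passed adjusted over the list alone. COR15B passed singly with an offset before the log (adjusted p = 0.0184). It also passed without WS before dawn replicate 2 (adjusted p = 0.0134), WS 60 min replicate 1 (0.0479), lhy cca1 before dawn replicate 1 (0.0401), or lhy cca1 30 min replicate 1 (0.0412) or 2 (0.0446). Over all probe sets limma called 0 of these 3, with 1021 probe sets at an unadjusted p under 0.05. The wider cold and dehydration list of 13 did not pass in the interaction at 60 min (camera adjusted p = 0.495). COR15A was dim in lhy cca1 before dawn and above the 40th percentile on 1 of 2 WS arrays, so its value rests partly on a dim signal. In WS at 60 min COR15A differed by 0.98 log2 (adjusted p = 0.136), COR15B by -0.47 (adjusted p = 0.311) and COR47 by -0.06 (adjusted p = 0.88), none past the threshold. Plastid-encoded genes were higher in the interaction at 15 min (adjusted p = 4.23e-06; adjusted p = 0.799 with an estimated correlation; list mean 0.412 ± 0.373 log2, and 0.241 ± 0.352 with 25S rRNA as a covariate) and nuclear photosynthesis genes lower at 30 min (adjusted p = 0.00279; adjusted p = 0.791 with an estimated correlation; 0.199 under quantile normalization).

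**Figure D4:**
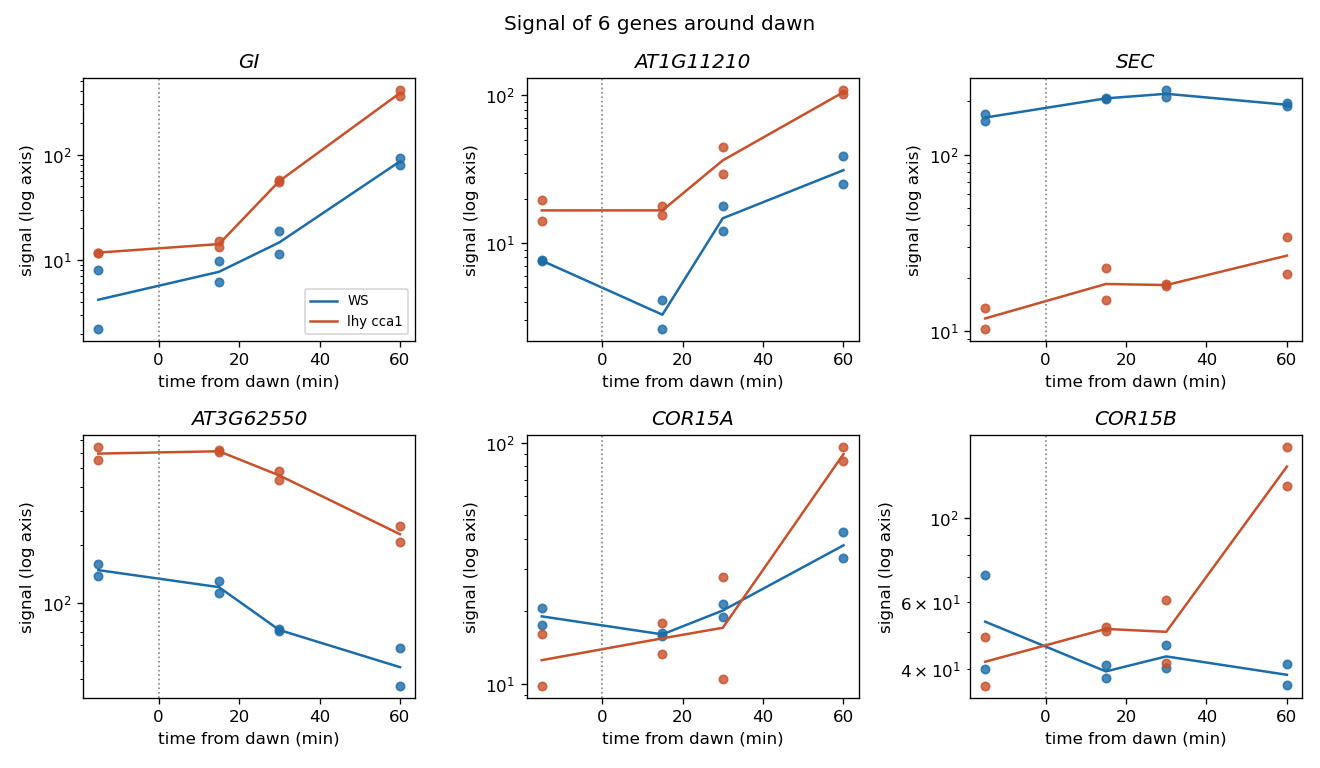
Signal per array (points, log axis) of GI, AT1G11210, SEC, AT3G62550, COR15A and COR15B against minutes from dawn in WS (blue) and lhy cca1 (orange); lines join means of the log values. At 60 min COR15B reached 121.5 and 153.5 in lhy cca1 and 36.13 and 41.12 in WS.

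Y candidates, which rose around dawn in WS and were higher in lhy cca1, comprised 5 probe sets, and GI and AT1G11210 were the named ones. The criteria used fitted means, in which dim signals count, and a rise around dawn is not shown to be induced by light. GI rose in WS as given above (adjusted p = 4.8e-06, at least 4.23-fold) and was higher in lhy cca1 by 2.15 log2 at 60 min. Its signal at 60 min was 86.33 ± 8.44 (SD, n = 2) in WS and 383.3 ± 31.3 (SD, n = 2) in lhy cca1. AT1G11210 rose at least 1.53-fold in WS at 60 min (adjusted p = 0.00145), to 31.9 ± 9.84 (SD, n = 2), and was higher in lhy cca1 by 1.76 ± 0.365 log2 at 60 min (adjusted p = 0.0136), at 105.1 ± 4.21 (SD, n = 2). It was dim in both genotypes before dawn and at 15 min, and dim in WS at 30 min. The rise of GI, from signals dim in both genotypes, was not shown to differ between them at 60 min (adjusted p = 0.888).

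The other candidates had no gene listed and were 248160_at (rise in WS at least 1.75-fold), 248910_at (higher at single times as given above, dim in WS before dawn, no fold of its rise to give) and 247252_at (higher by 1.29 log2, rise of 1.13 with adjusted p = 0.0462). At 30 and 60 min, when it was not dim, 248160_at differed between genotypes by 0.99 and 0.28 log2 (adjusted p = 0.41 and 0.81), so its genotype criterion rests partly on dim signals. The rise of 247252_at was lost without any of 11 arrays taken singly (adjusted p from 0.0571 to 0.494), and that of 248910_at without WS 60 min replicate 2 (adjusted p = 0.0593). Among 259 probe sets that rose at least 2-fold and 100 that were at least 2-fold higher, 1.74 would be shared by independent lists (Fisher's exact test, 2-sided p = 0.0305). Without the 2-fold criterion 55 were shared where 58.3 would be by independent lists (Fisher's exact test, 2-sided p = 0.724). With an offset of 20.51 added before the log, which shrinks differences of dim signals, 0 candidates met the 2-fold criterion in limma. GI was then higher in lhy cca1 by 0.92 log2 (adjusted p = 3.33e-07) and AT1G11210 by 0.75, each short of 2-fold. The count was 10 without WS before dawn replicate 1 and 8 without WS before dawn replicate 2.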

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

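The tests of why plastid-encoded genes were higher, of their list mean and of 25S rRNA were chosen only after the result was seen. The camera list tests were set before any fit, and the count of splits was planned.

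The dawn change of AT4G33380 differed between genotypes in the F test over the 3 times after dawn (adjusted p = 0.00709). In that test 4 probe sets passed, and at 60 min alone 3 did. With eBayes without the trend these counts were 0 and 1, and AT4G33380 had an adjusted p of 0.187. Without WS 30 min replicate 1 its adjusted p was 0.0714. Cold response genes, 3 of them tested, differed as a list at 60 min (camera adjusted p = 3.05e-05). The wider cold and dehydration list of 13 did not (camera adjusted p = 0.495). Nuclear photosynthesis genes differed as a list at 30 min (adjusted p = 0.00279). Plastid-encoded genes differed as a list at 15 min (adjusted p = 4.23e-06), when 25S rRNA in lhy cca1 went from 5.98 and 9.07 log2 to 7.98 and 9.15, and the list mean differed by 0.412 ± 0.373 log2 (0.241 ± 0.352 with 25S rRNA as a covariate). The latter pair of lists did not pass with an estimated correlation (adjusted p = 0.791 and 0.799).

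The 25S rRNA control probe set, left out of the main comparisons and used only as a covariate, was higher in lhy cca1 than in WS by 1.2 log2. Its mean was 6.79 in lhy cca1 replicate 1, 8.74 in lhy cca1 replicate 2 and 6.57 in WS.

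The count of 2709 probe sets that differed between genotypes was exceeded or equalled by 1 of 100 splits of the arrays within each time, the real one included. The highest other split gave 995, so the real count exceeded that of each other split run. The other splits mix WS and lhy cca1 arrays within a group, so any difference between the lines widens their spread and lowers their counts. The test therefore cannot tell an effect of the mutations from a difference in culture, extraction or labelling between the lines.

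Plastid-encoded genes were higher in lhy cca1, with a list mean 0.43 ± 0.126 log2 above WS. The authors' scaling was argued against by the list's median of 0.36 after quantile normalization (quartiles 0.179 to 0.629), whereas RNA degradation stays open, since the 3' to 5' log2 ratios differed within their spread, by -0.0503 for actin (95% interval -0.185 to 0.0845, exact permutation p = 0.439) and 0.0162 for GAPDH (-0.101 to 0.133, p = 0.767). Carry-over of RNA without poly(A) tails, which may raise rRNA and plastid transcripts together, stays open: with 25S rRNA as a covariate the difference was 0.258 ± 0.125 (95% interval -0.0202 to 0.537), and the slope on rRNA was 0.145 ± 0.0584. The difference is 2.07 standard errors from 0 and passed the bound of 2 first written, which was replaced after it was seen because the interval with so few arrays is wider and includes 0; a fit with the replicate number as a further term, given in the next part, left the difference above 0, but that number is not shown to pair the arrays. A biological effect of the mutations stays open and untested; without the 4 lhy cca1 replicate 2 arrays the difference was 0.244 ± 0.139.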

How the results depend on the processing

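Alternatives with 25S rRNA or without the lhy cca1 replicate 2 arrays were chosen only after the result was seen. So was the replicate number as a term for plastid-encoded genes. The others were planned. Those chosen later and the 2-fold criterion were not run for single named genes. Of 163 results for named genes, 108 kept their direction and side of the threshold under all alternatives run for them. A further 53 lost a call under at least 1, 1 gained a call and 1 turned its sign. Lost calls made up 330 of 3813 single values, 271 of them on leaving out an array, which leaves 1 sample in a group that is assumed to vary like the other groups. The sign of AT5G52660 between genotypes turned, at -0.03 with quantile normalization, -0.0103 with median centring, and ranged from -0.0601 (without WS 60 min replicate 1) to 0.105 (without WS 60 min replicate 2) on leaving out an array, with -0.0569 without WS 30 min replicate 1 and -0.012 without lhy cca1 15 min replicate 1. Of 457 values of the main counts 354 stayed within 1.5 times. Signals near the 40th percentile limit the differences of dim genes, and where no cause is named here, the cause was not tested.

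Quantile normalization, median centring and the 60th percentile filter kept all main counts within 1.5 times. An offset before the log, which shrinks dim signals, gave 8 probe sets for the interaction at 60 min (5 higher, 3 lower) and 0 Y candidates in limma. Without a filter 105 differed between genotypes at 30 min, with more probe sets tested. eBayes without the trend gave 124, 83, 66 and 317 for genotype before dawn and at 15, 30 and 60 min, 6 for WS and 0 for lhy cca1 at 15 min, 1 for the interaction at 60 min and 0 in its F test (611 at an unadjusted p under 0.05 with the trend). Fits of fewer samples used only the arrays of 1 time for genotype and all arrays of 1 genotype for dawn. They gave 647 and 88 for genotype at 15 and 60 min and 5 for WS at 15 min. The added 2-fold criterion gave 154 for the genotype mean, 99, 92, 79 and 186 at the single times, 184 and 568 for WS at 30 and 60 min (F test 537), and 154 and 622 for lhy cca1 (F test 571). Y candidates numbered 55 by adjusted p alone and 9 with a rise in either genotype. The 25S rRNA covariate gave 1182 for the genotype mean, 1151 of them shared with the 2709, and without lhy cca1 replicate 2 it was 872, 842 shared, with 297 for dawn in lhy cca1. List calls numbered 15 with camera's preset correlation, 1 with an estimated correlation, 26 with fry by direction and 58 with fry in either direction. With the replicate number as a block, camera's preset correlation gave 19.

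With the replicate number as a block, counts were 410, 434 and 254 for genotype before dawn and at 15 and 30 min, 30 for WS and 26 for lhy cca1 at 15 min, and 2 and 6 for the interaction at 30 and 60 min. The block changed no other main count by over 1.5 times. COR15B passed in the interaction at 60 min with the block (adjusted p = 0.0379, where its alternatives ranged from 0.0134 to 0.248). Deviations of same-numbered arrays correlated at -0.0163 to 0.269 over 28 pairs (median 0.103), 15 of them over 0.1 and 1 below 0. Each of the 8 groups correlated best with its own number on average, a hint from the data that the number pairs the arrays. The labels do not say what the number marks. The main fit, planned without it, ignores any such pairing. The plastid-encoded list mean was higher on the replicate 2 array in 8 of 8 groups. With the replicate number as a term its genotype difference was 0.431 ± 0.089 log2 (95% interval 0.233 to 0.63), and with 25S rRNA added 0.327 ± 0.101 (0.0978 to 0.555).

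Leaving out each array in turn gave 2037 to 2888 for the genotype mean, 45 to 370 before dawn, 25 to 407 at 15 min, 26 to 213 at 30 min and 141 to 480 at 60 min. For WS it gave 6 to 32, 149 to 416 and 822 to 1370 at 15, 30 and 60 min (F test 839 to 1070), and for lhy cca1 1 to 21, 135 to 315 and 797 to 1627 (F test 642 to 1184). The interaction gave 0 to 2, 0 to 3 and 1 to 12 (F test 1 to 7), and Y candidates 4 to 10. Single arrays moved counts by over 1.5 times mostly in their own contrasts: genotype before dawn was 62 and 119 without WS before dawn replicate 1 or 2; at 15 min 46 and 88 without WS 15 min replicate 1 or 2 and 80 without lhy cca1 15 min replicate 1; at 30 min 30 and 59 without WS 30 min replicate 1 or 2 and 79 without lhy cca1 30 min replicate 1. Without WS 60 min replicate 1 or 2, genotype was 368 and 370 before dawn and 407 at 15 min, WS at 15 min was 32, lhy cca1 at 15 min 19, and the interaction at 60 min 12 and 8. WS at 30 min was 169 and 182 without WS before dawn replicate 1 or 2, 149 and 160 without WS 30 min replicate 1 or 2, and at 15 min 11 without WS before dawn replicate 1, 6 without either WS 15 min array and 12 without either lhy cca1 array before dawn. For lhy cca1, 15 min gave 21 without its before dawn replicate 1, 2 and 1 without its 15 min replicate 1 or 2; 30 min gave 135 without its 30 min replicate 1 and 140 without its before dawn replicate 2; and the F test gave 642 without its 60 min replicate 1. The interaction at 60 min gave 5 without WS before dawn replicate 2 or either lhy cca1 30 min array, 8 without lhy cca1 before dawn replicate 1, and 1 without lhy cca1 before dawn replicate 2 or 60 min replicate 2. Its F test gave 2 without WS before dawn replicate 2, WS 15 min replicate 2 or either lhy cca1 60 min array.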

Other observations

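The tests of neighbouring genes and of opposing dawn changes were chosen only after the result was seen.

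Of 8 tested iron regulation genes, 2 rose and 1 fell at 60 min in WS, and 1 rose and 1 fell in lhy cca1. By camera the list did not pass (adjusted p = 0.437 in WS and 0.874 in lhy cca1). By fry it passed in either direction (adjusted p = 2.44e-07 and 1.68e-07) but not by direction (adjusted p = 0.454 and 0.89). PYE, a transcription factor gene of the iron deficiency response, rose by 1.37 ± 0.215 log2 in WS and by 1.45 ± 0.215 in lhy cca1. The related regulator gene bHLH121 fell by 1.46 ± 0.178 in WS and fell by 1.73 ± 0.178 in lhy cca1. MYC4, a jasmonate-response transcription factor gene on the glucosinolate list, rose by 1.02 ± 0.171 in lhy cca1, where 2 of 11 members of that list rose (list adjusted p = 0.0836). GTR1, a glucosinolate transporter gene, was lower in lhy cca1 in the mean over 4 times, at -0.53 ± 0.0711, as was GSTU20, a glutathione transferase gene, at -0.45 ± 0.089. The wall genes XTH32 (-0.78 ± 0.069) and XTH19 (0.60 ± 0.104) differed in opposite directions. ATG8F, of autophagy, was higher at 0.41 ± 0.0687 and the starch branching enzyme gene SBE2.2 at 0.56 ± 0.109.

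Markers of roots and reference genes did not differ between genotypes in limma over all genes or adjusted over the list alone, with 0 of 3 past the threshold in each list and 4683 of all probe sets at an unadjusted p under 0.05. The root markers EXPA18 and PYK10 differed by -0.06 ± 0.172 and 0.13 ± 0.0803 log2, and EXPA7 was dim in 6 of 8 groups. The reference genes AT2G28390, AT4G34270 and PEX4 differed by -0.20 ± 0.0774, 0.01 ± 0.109 and -0.05 ± 0.0691.

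SEC and its neighbour AT3G04230 were both lower in lhy cca1, which raised the hypothesis that a linked chromosome region differs between the lines. Among 75 genes at least 2-fold different between genotypes, 3 pairs lay within 5 genes of each other, where random sets had a median of 1 and 9.45% of them held as many. Equal sets of genes changed at dawn held as many in 7.86% of draws (9.77% with genes changed in either genotype). Random sets could therefore give as many pairs, and the sets of dawn-changed genes held as many about as often. With so few pairs, neither a linked region nor shared regulation of neighbours can be told apart from chance. Pairs were counted over all named genes, so the region of SEC itself was not tested.

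Genotype differences ran against the dawn change, taken at 60 min as the mean of both genotypes: across probe sets, which are not independent, their correlation was -0.191. It was below 0 at 4 of 4 times (-0.139, -0.15, -0.196 and -0.135), which argues against a difference that rests on 1 sampling time. At 15 and 30 min the 2 quantities share no array, and before dawn and at 60 min noise of the observed spread would give a covariance of -0.0023 and -0.00856, where -0.026 and -0.0271 were seen. Among 1405 probe sets changed at dawn, 35.3% of those that rose and 64.7% of those that fell were higher in lhy cca1. Of 100 splits of the arrays within each time, 9, the real one included, gave a correlation as far from 0, with 0.226 the highest other, so chance is not excluded. That lhy cca1 seedlings may lag behind WS around dawn stays a hypothesis that these data do not decide.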
